A study of Sus scrofa with 63 samples.

How the data were processed

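Skin RNA was measured on 63 Affymetrix GeneChip Porcine Genome arrays, 1 array per biopsy. Arrays fell into 27 groups, 3 exposed and 3 control arrays and 1 sham array at each of 9 times. The deposited values are log2 signals per probe set, made by the authors with RMA, and Partek is also named in the submitters' processing notes; neither has a version there. They ranged from 4.05 to 14.54, and the medians of the 63 columns lay between 7.75 and 7.862, so no further scaling was applied. RMA compresses differences of dim probe sets, so fold changes of genes near the lower end of the scale are lower than those in the RNA. Of 24123 probe sets 124 controls were left out and 23999 were tested. An array has no read depth; the SD of the difference between 2 arrays of a group over probe sets was 0.231 to 0.583, with a median of 0.335.

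Gene symbols came from the supplied annotation of the array, which listed 10297 of the probe sets. Of these 10099 had 1 symbol and 198 several, and 13826 were not listed and have no name here. Of the symbols 9989 were matched by gene number to RefSeq genes of the Sscrofa11.1 assembly, which also gave gene length. Where a gene had several probe sets (2261 of 6765 genes), the one with the highest mean over all arrays was used.

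All arrays were fitted together in limma 3.58.1 (R 4.3.3, data.table, version 1.17.8) with 1 mean per group, 36 residual and 3.24 prior degrees of freedom. Contrasts were exposed minus control at each time, their mean over 3 windows (1 to 4 h, 24 to 72 h, 168 to 514 h, 9 exposed and 9 control arrays each), the 2 differences between successive windows, a moderated F test of any difference among the 9 times, and sham minus control averaged over the 9 times. P values were adjusted by Benjamini-Hochberg over the 23999 probe sets, with a threshold of 0.05, two-sided. Sham groups of 1 array add no residual degrees of freedom, and the fit takes them to vary like the other groups. The arrays were processed in 3 periods, each holding the arrays of 1 time of every window, so windows are balanced over periods but single times are not.

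The 27 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. Lists had to hold at least 5 measured genes to be tested, which left 26. They were tested with camera at a preset correlation of 0.01, and, as alternatives, with camera at an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the genes of a list move, on balance, one way. Adjusted p values of lists are over the 26 lists of a comparison. For each list, counts of genes are given over all probe sets tested and adjusted over the list alone. In these counts a gene rose or fell only where it passed the threshold. PCNA stands in both the DNA repair and the cell cycle list. Genes were named by rule: for each window the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign at its 3 times; for each time the 2 largest in each direction with the same sign in 3 pairs; for each list and window up to 3 members with the largest change past the threshold, or 1 where none passed; and the 5 largest in each direction for sham and for the differences between windows. Of these, a gene that held by a narrow margin is not always printed. Muscle content was summarised by the mean log2 value of the measured skeletal muscle genes of an array, the muscle score. RNA integrity was summarised by the difference between the 3 prime and 5 prime control probe sets of GAPDH, actin and EF1A. Over the 63 arrays the GAPDH difference followed the muscle score (r = -0.82), so it does not measure integrity alone; r was 0.233 for actin and -0.0657 for EF1A. Both were compared between exposed and control arrays by exact permutation within times, 12 comparisons in all, and for the integrity measures the adjusted p was 0.643 to 0.851.

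At each time 3 animals gave the exposed and the control sites and a 4th was the sham. Whether the replicate number marks an animal is not stated. All 27 pairs of exposed and control arrays with the same number shared a sacrifice day, and replicate 3 alone had another day at all 9 times. Residuals of same-numbered arrays correlated over probe sets with a mean r of 0.27, against -0.136 for other numbers. Residuals cancel within a group of 3 arrays, so the value for other numbers follows from the first and is no separate evidence. For the same number 21 of 27 pairs had r over 0.1, at 5 of 9 times all 3. A fit with this number as a block is one of the alternatives, and was fitted on exposed and control arrays.

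The procedure was tested on simulated data with the same groups of arrays. The simulated noise was independent between probe sets and between arrays, without pair effects or differences in muscle content. The rates below thus need not hold for the real arrays, where probe sets and same-numbered arrays are correlated. At a true log2 change of 0.5, 1 and 2 the fit recovered 46.3%, 86.6% and 100% of the changed probe sets at 24 h, 88.1%, 98.5% and 100% in the window of 24 to 72 h, and 62.7%, 97% and 100% for the difference between windows. Of 164 calls at 24 h 9 were false, and of 205 in the window 14; with no change put in, limma made 0 calls for the window of 1 to 4 h and 0 for sham.

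The alternatives chosen in advance were quantile normalization applied again, centring each array on its median, leaving out probe sets below the 40th percentile of the mean, an intensity trend with robust estimation, an adjusted p of 0.01, an added log2 change of at least 1, a fit on the arrays compared alone, the replicate block, the in vitro transcription or RNA extraction batch as a covariate, control and sham merged, the mean of all probe sets of a gene, and leaving out each array in turn. A covariate for the muscle score and the use of sham arrays as the control group were added after seeing the data. Other splits of the arrays were counted, all 10 for a time and 100 random splits for each other result. For the windows, exposed and control arrays were also exchanged within same-numbered pairs.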

Results

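Gene expression was measured in abdominal skin of female Yorkshire crossbred pigs after exposure to sulfur mustard, an alkylating blister agent. Lesions of 3 cm were made with 400 µL of neat agent applied for 8 min. Punch biopsies of 8 mm were taken at 1, 2, 4, 24, 48, 72, 168, 336 and 514 h. The labels give the last time as 514 h, while the design text gives it in days as a slightly earlier time. At each time there were 3 arrays of exposed sites, 3 of unexposed control sites and 1 of a sham animal that was prepared but not exposed, 63 arrays in all. By the design text these came from 4 animals at each time, 3 of which gave both exposed and control sites, while the fit takes arrays as independent. Each array was hybridized with cRNA made from 10 µg of total RNA. Array medians lay between 7.75 and 7.862 on the log2 scale, and the number of arrays limits the precision. For each gene named below, ± gives the standard error of the difference from the limma fit, and a pair is an exposed and a control array with the same replicate number. This standard error uses 1 spread pooled over all groups, so at single times it need not match the spread of the 3 pairs.

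The histology scores in the labels describe the depth of injury. At 1 and 2 h all 5 scores of the exposed sites were 0. At 4 h dermal necrosis scored 1 in each of the 3 exposed sites. At 24, 48 and 72 h epidermal necrosis had a mean score of 4, 4 and 3.67, and dermal necrosis 4 at each of these times (n = 3). Control and sham sites scored 0 on these scales. Another scale was used from 168 h, on which normal skin scores 13. Exposed sites had a total of 7 ± 1.73 (SD, n = 3) at 168 h, 7 ± 2.65 at 336 h and 7.33 ± 1.53 at 514 h. The score for complete re-epithelialization was 0 in all 3 exposed sites at 168 h and 1 in all 3 at 514 h.

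The comparison of exposed with control sites at each time asked when and how strongly the skin responded. The count of probe sets past an adjusted p of 0.05 in limma was 288 at 1 h, 94 at 2 h and 348 at 4 h, and 6507 at 24 h, of 23999 tested. It was 2387 at 48 h, 2317 at 72 h, 4304 at 168 h, 970 at 336 h and 1398 at 514 h. Arrays of 1, 24 and 168 h were processed in 1 period. Those of 2, 48 and 336 h were in another, and those of 4, 72 and 514 h in the last. Each comparison lies within a time. Differences in count between times of different periods cannot be told apart from an effect of the period. More probe sets were higher than lower at all times except 1 h, where 99 were higher and 189 lower. That direction did not hold in every fit: without control 1 it was 46 higher and 39 lower at 1 h and 283 and 315 at 4 h, with a log2 change of at least 1 it was 45 and 10 at 1 h, and with the muscle score as a covariate 3509 and 3520 at 24 h. With the replicate number as a block the counts were 436 at 1 h, 149 at 2 h, 606 at 4 h, 1736 at 336 h and 2162 at 514 h.

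**Figure D1:**
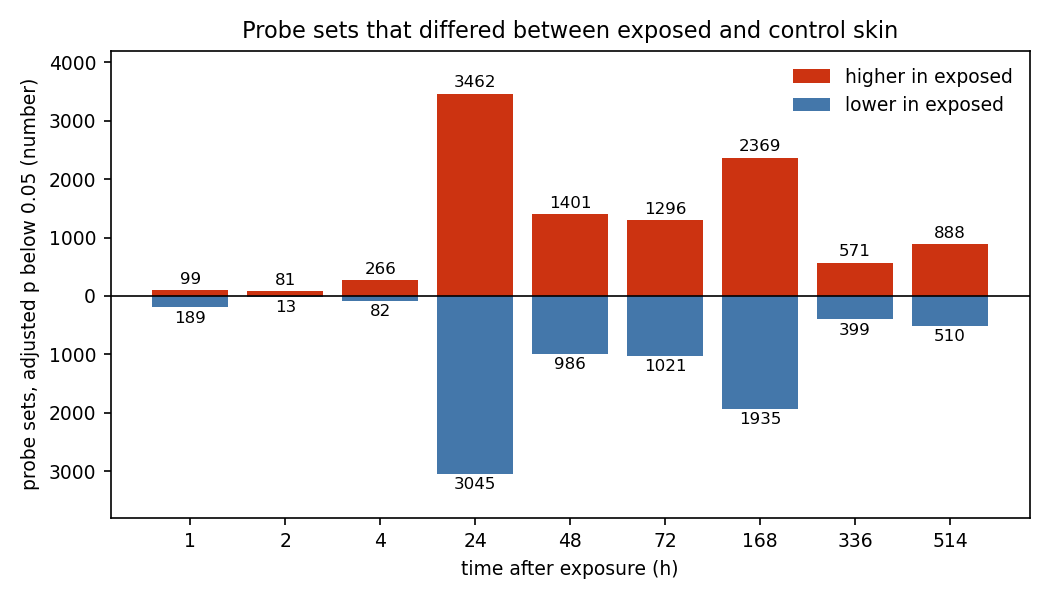
Bars give the number of probe sets with an adjusted p below 0.05 between 3 exposed and 3 control arrays at each time after exposure (h), higher in exposed sites above 0 and lower below 0. The largest counts are at 24 h (3462 higher, 3045 lower) and 168 h (2369 higher, 1935 lower). Arrays of 1, 24 and 168 h were processed in 1 period, and those of the other times in others.

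At 1 to 4 h the genes with the largest rise included transcription factors of the immediate early response and chemokines. FOS, a subunit of the AP-1 transcription factor, rose by 2.60 ± 0.36 on the log2 scale (6.06-fold, 9 of 9 pairs, adjusted p = 3.36e-06). EGR1 rose by 2.22 ± 0.27, ATF3 by 1.95 ± 0.22, NR4A2 by 1.72 ± 0.28 and BTG2, an antiproliferative gene, by 1.65 ± 0.22, each in 9 of 9 pairs. CYR61, which encodes a secreted matrix protein, rose by 2.53 ± 0.27 (adjusted p = 7.69e-09). Among genes of leukocyte recruitment, CXCL2 rose by 2.00 ± 0.27, CCL2 by 1.91 ± 0.21, CCL8 by 1.90 ± 0.27 and CCL4 by 1.86 ± 0.24. The cytokine gene IL6 rose by 1.71 ± 0.21 in 8 of 9 pairs, and PTGS2, the inducible cyclooxygenase, by 1.59 ± 0.21 in 9 of 9.

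Fewer genes fell by a large amount in this window. GATA3, a transcription factor of epidermal and hair follicle differentiation, fell by 0.86 ± 0.14 (9 of 9 pairs, adjusted p = 2.97e-05). The growth factor receptor gene FGFR2 fell by 0.67 ± 0.13 in 8 of 9 pairs, the transporter gene SLCO3A1 by 0.60 ± 0.10, and MGAT5, a glycosyltransferase gene, by 0.58 ± 0.10 in 9 of 9. The activin receptor gene ACVR2A fell by 0.56 ± 0.11 in 8 of 9 pairs, and KDM6A, a histone demethylase gene, by 0.50 ± 0.11 in 9 of 9. HOXA9 fell by 1.34 ± 0.19 (9 of 9 pairs, adjusted p = 4.64e-06), and it was lower in sham than in control sites as well (-1.74 ± 0.16), so that against sham arrays it differed by 0.105. In all, 496 probe sets were higher and 819 lower at 1 to 4 h, and 68 and 2 of these changed by at least 2-fold. With sham arrays as the control group, 3 in the window, 171 were higher and 129 lower. With fewer arrays the standard error is larger (0.259 against 0.19 for HOXA9), and most lower probe sets changed by less than 2-fold. These counts thus do not show whether the excess of lower probe sets depends on the control group.

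Of the 26 gene lists tested, 6 shifted upwards at 1 to 4 h in camera and 0 downwards; camera with an estimated correlation called 3, with 4 at an unadjusted p below 0.05. With the replicate number as a block camera called 7, these 6 and the basal keratinocyte list, downwards (median -0.0781, adjusted p = 0.0373), a list that fry called too (adjusted p = 0.0473) and that was not called without the block at an estimated correlation (adjusted p = 0.303). In the immediate early list 11 of 14 measured genes rose, and 13 when adjusted over the list alone (median 1.29, adjusted p = 5.37e-32). Of 33 genes for inflammatory cytokines, chemokines and adhesion, 12 rose, and 16 when adjusted over the list alone (median 0.32, adjusted p = 1.28e-15). Of 16 targets of p53, 4 rose, and 6 when adjusted over the list alone (median 0.128, adjusted p = 0.000947). They were GADD45A (1.44 ± 0.13), PMAIP1 (1.08 ± 0.18), PLK2 (0.87 ± 0.11) and CDKN1A, the cell cycle inhibitor p21 (0.58), which was chosen after its value was seen. These 3 lists kept their call with an estimated correlation, at an adjusted p of 0.000222, 0.0181 and 0.0181. The calls of the heat shock list and of the next 2 lists were lost. In the heat shock list 6 of 18 genes rose, and 10 when adjusted over the list alone, led by DDIT3 (0.83 ± 0.13), with adjusted p = 3.24e-07 and adjusted p = 0.0766 with an estimated correlation. In the list of matrix proteases 2 of 23 rose, and 3 when adjusted over the list alone, ADAMTS1 (0.86 ± 0.11) and PLAU (0.74 ± 0.11), with adjusted p = 0.039 and adjusted p = 0.431 with an estimated correlation. In the list of NRF2 targets and metallothioneins 0 of 18 genes passed in limma, 4 had an unadjusted p below 0.05, and the median was 0.117 (camera adjusted p = 0.039, adjusted p = 0.303 with an estimated correlation). The calls of the protease and NRF2 lists were also lost with quantile normalization applied again, and in 9 and 10 of 18 fits that left out 1 array.

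Among the other lists at 1 to 4 h, single genes passed. AREG, an epidermal growth factor receptor ligand, rose by 0.69 ± 0.14, THBS1, the thrombospondin gene, by 1.44 ± 0.20, and NFIL3, a transcription factor of the circadian list, by 0.85 ± 0.16. In the cell cycle list CKS2 rose by 0.55 ± 0.10 and PCNA by 0.41 ± 0.08, while CDC25B fell by 0.38 ± 0.07 (median of 26 genes -0.0624, camera adjusted p = 0.132). Neutrophil and macrophage markers had a median of 0.113 (adjusted p = 0.456) and differentiated keratinocyte genes a median of -0.153 (adjusted p = 0.224). The lists of basal keratinocyte, DNA repair, interferon, complement, antigen presentation, lymphocyte, activated keratinocyte, epidermal lipid, hair follicle, melanocyte, fibroblast, endothelial, smooth muscle, adipocyte, apoptosis and circadian genes also missed the threshold, with adjusted p from 0.0781 to 0.938. Camera's direction differed from the sign of the median for DNA repair (-0.00145, up) and hair follicle genes (0.0131, down), and from that of the mean for epidermal lipid (0.00279, down) and fibroblast genes (0.0772, down). Skeletal muscle genes had a median of 0.514 (adjusted p = 0.491), and the muscle score, which is the mean log2 value of these genes on an array, was 11.5 ± 2.43 (SD, n = 9) in exposed and 11 ± 2.42 in control arrays.

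At 1 h CYR61 rose by 3.01 ± 0.46 and FOS by 2.85 ± 0.63, at 2 h CYR61 by 2.51 ± 0.46 and CCL8 by 2.41 ± 0.46, and at 4 h IL6 by 3.16 ± 0.37 and FOS by 2.92 ± 0.63, each in 3 of 3 pairs. The rule for naming genes at a single time required 3 of 3 pairs, so that count is no separate evidence. HOXA9 fell by 1.65 ± 0.33 at 1 h and by 1.47 ± 0.33 at 2 h, and GATA3 by 1.11 ± 0.24 at 1 h. At 4 h the genes HOXD12 (-0.99 ± 0.23) and MEIS1 (-0.79 ± 0.19) were lower, and these calls were lost in 3 and 4 of 6 fits that left out 1 array. Fitted on the 6 arrays of the time alone, limma called 1 probe set at 1 h, 0 at 2 h (1180 at an unadjusted p below 0.05) and 60 at 4 h, and of the genes named here only IL6 and FOS at 4 h stayed past the threshold. Leaving out 1 array moved the count at 1 h to 151 (exposed 1), 111 (exposed 3), 85 (control 1), 173 (control 2) or 461 (control 3), at 2 h to 50 (exposed 2) or 47 (control 1), and at 4 h to 598 (control 1) or 218 (control 2).

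**Figure D2:**
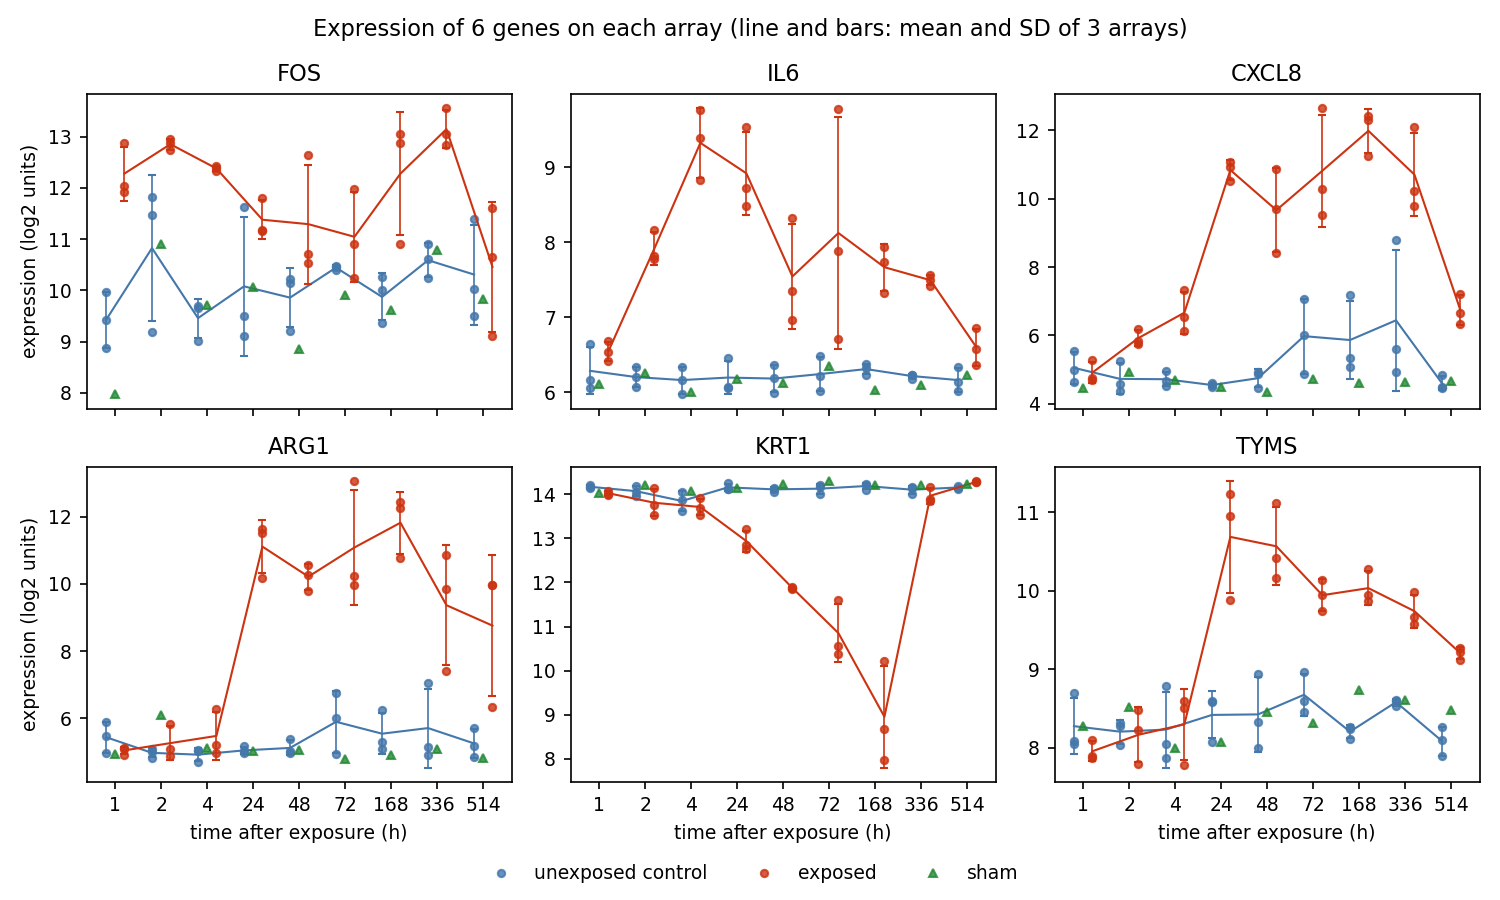
Expression (log2 units) of FOS, IL6, CXCL8, ARG1, KRT1 and TYMS on each array against time after exposure (h), with exposed, unexposed control and sham arrays as points; lines and bars give the mean and SD of 3 exposed or 3 control arrays. IL6 in exposed sites has its largest difference from control at 4 h (3.16), and KRT1 at 168 h (-5.23).

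At 24 to 72 h ARG1, the arginase gene, rose by 5.45 ± 0.43 (43.6-fold, 9 of 9 pairs, adjusted p = 5.64e-13). The neutrophil chemokine gene CXCL8 rose by 5.35 ± 0.40 (40.8-fold), and PPBP, a platelet chemokine gene, by 4.72 ± 0.29 (26.4-fold). TNC, which encodes the wound matrix protein tenascin C, rose by 3.45 ± 0.23. SDS, encoding serine dehydratase, rose by 3.28 ± 0.33, CXCL2 by 3.22 ± 0.27 and PTX3, the long pentraxin gene, by 3.11 ± 0.20. SLC11A1, a macrophage metal transporter gene, rose by 2.94 ± 0.15, SPP1, the osteopontin gene, by 2.89 ± 0.29, the chemokine receptor gene CCR1 by 2.88 ± 0.16, the collagenase gene MMP1 by 2.85 ± 0.33 and CDA by 2.81 ± 0.20. Each of these rose in 9 of 9 pairs.

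Among the largest falls at 24 to 72 h, SULT1E1, the estrogen sulfotransferase gene, fell by 3.44 ± 0.25 and the epidermal serpin gene SERPINB7 by 3.17 ± 0.20. CALML5, a calmodulin-like gene of differentiating keratinocytes, fell by 3.12 ± 0.19, and the suprabasal keratin genes KRT2 and KRT1 fell by 2.61 ± 0.35 and 2.25 ± 0.15. STMN2, a neuronal stathmin gene, fell by 2.77 ± 0.27, CCL28, an epithelial chemokine gene, by 2.33 ± 0.21, GATA3 by 2.13 ± 0.14 and HOPX by 1.99 ± 0.14. HOXA9, which was also lower in sham sites (-1.74 ± 0.16), fell by 2.25 ± 0.19, and against sham arrays its call was lost (-0.51). ABHD12B fell by 1.97 ± 0.20 and C1QTNF3 by 1.91 ± 0.27, and all 12 were lower in 9 of 9 pairs. The comparison called 8432 probe sets, 4378 higher and 4054 lower, of which 292 and 228 changed by at least 2-fold. It was 4273 and 4332 with the muscle score as a covariate, and 3348 and 3445 with sham arrays as the control group.

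In camera 8 lists shifted upwards and 5 downwards at 24 to 72 h. With the replicate number as a block 9 and 6 did, the added lists being interferon-stimulated genes, upwards (adjusted p = 0.0151), and circadian genes, downwards (adjusted p = 0.0387); without the block neither was called at an estimated correlation (adjusted p = 0.744 and 0.182). Of 16 p53 targets 10 rose, and 11 when adjusted over the list alone (median 0.592, adjusted p = 0.00083, adjusted p = 0.0359 with an estimated correlation). GADD45A rose by 1.79 ± 0.13, ZMAT3 by 1.53 ± 0.19 and CDKN1A by 1.51 ± 0.09, each in 9 of 9 pairs, while DDB2, a DNA damage recognition gene chosen after its value was seen, fell by 0.87. Of 13 genes of differentiated keratinocytes and the cornified envelope 12 fell, the same count as when adjusted over the list alone (median -0.876, adjusted p = 3.17e-11, adjusted p = 0.047 with an estimated correlation). The 11 other calls were lost with an estimated correlation. Of 22 neutrophil and macrophage markers 19 rose, the same count as when adjusted over the list alone, with S100A9 at 2.74 ± 0.40, NCF4 at 1.72 ± 0.16 and CD163 at 1.59 ± 0.22 (adjusted p = 3.91e-08, adjusted p = 0.165 with an estimated correlation). Of 33 inflammatory genes 21 rose and 1 fell, and 22 rose when adjusted over the list alone (adjusted p = 0.00083, adjusted p = 0.36 with an estimated correlation). Of 23 protease genes 12 rose, the same count as when adjusted over the list alone, among them TIMP1 (2.06 ± 0.13) and PLAU (1.54 ± 0.11), with adjusted p = 0.0039 and adjusted p = 0.182 with an estimated correlation. In the list of NRF2 targets and metallothioneins 13 of 18 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.00941, adjusted p = 0.182 with an estimated correlation). HMOX1, heme oxygenase, rose by 2.26 ± 0.13, SOD2 by 1.63 ± 0.17 and NQO1 by 1.32 ± 0.19, and the 2 that fell were the metallothionein genes MT3 (-1.12) and MT1A (-0.82), chosen after their values were seen.

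Of 18 heat shock genes 11 rose and 1 fell, as when adjusted over the list alone, with CRYAB at 1.17 ± 0.25 (adjusted p = 0.0116, adjusted p = 0.419 with an estimated correlation). That call was also lost with the mean of all probe sets of a gene. Of 18 complement and acute phase genes 10 rose and 1 fell, and 12 and 1 when adjusted over the list alone, with CFB at 1.91 ± 0.15 and C3 at 1.56 ± 0.28 (adjusted p = 0.0141, adjusted p = 0.419 with an estimated correlation). Of 26 cell cycle genes 16 rose, and 18 rose and 1 fell when adjusted over the list alone, with TYMS, thymidylate synthase, at 1.89 ± 0.15 and UBE2C at 0.70 ± 0.11 (adjusted p = 0.00462, adjusted p = 0.419 with an estimated correlation). Of the list 3 rose and 4 fell at 24 h (median -0.077), 16 rose at 48 h and 13 at 72 h (medians 0.511 and 0.455), while TYMS rose at all 3 times, by 2.267, 2.144 and 1.265; the list was not tested for a difference between these times. Of 6 basal keratinocyte genes 3 fell, as when adjusted over the list alone, COL7A1 by 1.15 ± 0.15, DST by 0.90 ± 0.09 and COL17A1 by 0.35 ± 0.09 (adjusted p = 0.00941, adjusted p = 0.165 with an estimated correlation). Of 22 fibroblast and matrix genes 4 rose and 11 fell, and 4 and 12 when adjusted over the list alone. Their median was -0.25 and their mean 0.00663, and camera gave a downward shift (adjusted p = 0.0102, adjusted p = 0.423 with an estimated correlation). TNC and THBS1 (1.77 ± 0.20) rose and ASPN, the asporin gene, fell by 0.91 ± 0.16. Of 12 smooth muscle and pericyte genes 4 fell, and 9 when adjusted over the list alone, among them RGS5 (-0.45 ± 0.15), a call that was lost without exposed 48 h replicate 3, and DES (-1.04 ± 0.39) (adjusted p = 0.00941, adjusted p = 0.182 with an estimated correlation). DES is also made by skeletal muscle, and with the muscle score as a covariate its call was lost, as it was in 7 of 18 fits that left out 1 array and with sham arrays as the control group, where it turned in direction (0.014).

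Of the 22 skeletal muscle genes 0 passed in limma at 24 to 72 h, 4 had an unadjusted p below 0.05, and the median was -1.74 (camera adjusted p = 0.00083, adjusted p = 0.548 with an estimated correlation). With the replicate number as a block the muscle gene NEB was called lower. The muscle score was 9.9 ± 1.96 (SD, n = 9) in exposed and 11.6 ± 1.19 in control arrays, a difference of -1.7 (exact permutation within times, p = 0.0107, adjusted p = 0.128 over the 12 measures of this kind). That permutation did not use the pairs. The remaining lists did not pass in camera. In the DNA repair list 7 of 16 rose and 1 fell, and 8 and 2 when adjusted over the list alone (adjusted p = 0.12). MGMT, which removes alkyl groups from DNA, rose by 1.49 ± 0.11 and PCNA by 1.17 ± 0.08, both in 9 of 9 pairs. Interferon-stimulated genes had a median of 0.512 (8 of 19 rose, as when adjusted over the list alone, adjusted p = 0.196), with IFIT3 at 1.28 ± 0.34. In the circadian list NFIL3 rose by 0.97 ± 0.16 and CRY2 and DBP fell by 0.80 ± 0.10 and 0.65 ± 0.09 (median -0.343, adjusted p = 0.0917). AREG rose by 1.41 ± 0.14 and DEFB1, a beta-defensin gene, fell by 0.87 ± 0.13 in the activated keratinocyte list (adjusted p = 0.458). Immediate early genes had a median of 0.472 and an adjusted p of 0.182, with FOSL2 at 1.28 ± 0.14. The adjusted p was 0.185 for apoptosis regulators (CASP1 rose by 0.94 ± 0.23) and 0.126 for hair follicle genes (GATA3 as above). It was 0.676 for endothelial genes, whose median was 0.0555 while camera's direction was down. Lymphocyte (median 0.189), antigen presentation (0.277), epidermal lipid (0.0421, camera down) and adipocyte genes (-0.0707, mean 0.0251) each had an adjusted p of 0.458, and melanocyte markers (median 0.0202, camera down) an adjusted p of 0.479.

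At 24 h CXCL8 rose by 6.29 ± 0.70 and ARG1 by 6.06 ± 0.74 (n = 3 pairs), at 48 h ARG1 by 5.10 ± 0.74 and CXCL8 by 4.91 ± 0.70, and at 72 h ARG1 by 5.18 ± 0.74 and CXCL8 by 4.84 ± 0.70. SULT1E1 (-3.69 ± 0.44) and SERPINB7 (-3.06 ± 0.35) had the largest falls at 48 h, and STMN2 (-3.43 ± 0.47) and KRT1 (-3.28 ± 0.27) at 72 h. At 24 h the largest falls were in the muscle genes MYL1 (-5.02 ± 1.86) and CKM (-3.87 ± 1.42), and both calls were lost in 5 of the 6 fits that left out 1 array, all but the one without exposed replicate 1. The count at 48 h was 1097 without control 2 and 1221 without exposed 3, and at 72 h 1081 without exposed 3.

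In the window of 168 to 514 h ARG1 rose by 4.48 ± 0.43 (22.3-fold), CXCL8 by 4.17 ± 0.40 (18.1-fold) and MMP1 by 3.91 ± 0.33 (15-fold), each in 9 of 9 pairs. S100A9, a neutrophil calcium-binding protein gene, rose by 3.85 ± 0.40, CXCL2 by 2.76 ± 0.27 (8 of 9 pairs), TNC by 2.71 ± 0.23, TCN1, a vitamin B12 binding protein gene, by 2.63 ± 0.28, LOC396781 by 2.62 ± 0.57 and CDA by 2.50 ± 0.20. HPD rose by 2.46 ± 0.39, LTF, the lactoferrin gene, by 2.44 ± 0.27 and CYP2C91 by 2.40 ± 0.18. KRT2 fell by 2.58 ± 0.35 (7 of 9 pairs), QPCT by 2.15 ± 0.14, the ferritin receptor gene SCARA5 by 2.12 ± 0.17, C1QTNF3 by 1.73 ± 0.27 (8 of 9 pairs) and ABHD12B by 1.67 ± 0.20. MYOC, the myocilin gene, fell by 1.60 ± 0.22 and AGT, the angiotensinogen gene, by 1.58 ± 0.19. HOXA9 fell by 1.81 ± 0.19, and its sham value was -1.74 ± 0.16; against sham arrays it differed by 0.224. The comparison called 5262 probe sets, 2891 higher and 2371 lower, of which 221 and 123 changed by at least 2-fold. With the muscle score as a covariate 4440 of the 5262 (84.4%) were still called in the same direction. At 514 h alone it was 1156 of 1398 (82.7%).

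The genes CKM (-2.37 ± 0.82), TNNC1 (-2.16 ± 0.79), PPP1R1A (-1.78 ± 0.51) and PDLIM3 (-1.69 ± 0.54) also fell at 168 to 514 h, as did CA3 (-1.05 ± 0.33). CKM, TNNC1 and CA3 belong to the skeletal muscle list, in which 3 of 22 genes fell, and 0 when adjusted over the list alone (12 at an unadjusted p below 0.05). That list had a median of -2.03 (adjusted p = 7.53e-05, adjusted p = 0.443 with an estimated correlation), and the muscle score was 8.14 ± 1.54 (SD, n = 9) in exposed and 10.1 ± 2.7 in control arrays (exact permutation within times, p = 0.0802, adjusted p = 0.481). With the muscle score as a covariate the call of PDLIM3 was lost and that of PPP1R1A was not. CKM, TNNC1 and CA3 are part of that score, so the covariate cannot test them. With sham arrays as the control group all 5 calls were lost, and CKM (0.093) and TNNC1 (0.055) turned in direction. Of 18 fits that left out 1 array the call was lost in 8 for CKM and 11 for TNNC1. It was lost without control 168 h replicate 3, control 336 h replicate 1 or control 514 h replicate 1 for PDLIM3, and without exposed 168 h replicate 1, control 514 h replicate 1 or exposed 514 h replicate 3 for CA3.

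In camera 11 lists shifted upwards and 3 downwards at 168 to 514 h. With the replicate number as a block 13 and 3 did, the added lists being lymphocyte markers (adjusted p = 0.0498) and apoptosis regulators (adjusted p = 0.033), both upwards; without the block neither was called at an estimated correlation (adjusted p = 0.517 and 0.325). Only the call of the matrix proteases held with an estimated correlation (adjusted p = 1.44e-08, adjusted p = 0.0178 with an estimated correlation). Of its 23 genes 15 rose, and 16 when adjusted over the list alone, with SLPI, a leukocyte protease inhibitor gene, at 1.18 ± 0.21 and PLAU at 1.15 ± 0.11. The number that rose was 15 at 168 h, 8 at 336 h and 3 at 514 h (medians 0.602, 0.509 and 0.298). Of 26 cell cycle genes 21 rose, and 22 when adjusted over the list alone, with TYMS at 1.37 ± 0.15, RRM2 at 1.24 ± 0.14 and CCNB1 at 1.10 ± 0.13 (adjusted p = 2.89e-13, adjusted p = 0.0641 with an estimated correlation). Of 22 neutrophil and macrophage markers 19 rose, as when adjusted over the list alone, with S100A12 at 1.85 ± 0.21 and S100A8 at 1.43 ± 0.17 (adjusted p = 3.58e-10, adjusted p = 0.0832 with an estimated correlation). Of these markers 19 rose at 168 h, 8 at 336 h and 3 at 514 h (medians 1.692, 0.692 and 0.043). Of 33 inflammatory genes 18 rose and 1 fell, and 21 and 2 when adjusted over the list alone, with CCL8 at 2.12 ± 0.27 (adjusted p = 7.7e-06, adjusted p = 0.225 with an estimated correlation). At 168 h and 336 h 18 and 11 rose, and at 514 h 0 rose and 1 fell (medians 0.93, 0.611 and 0.058). At 514 h CXCL8 missed the threshold, though it lay at 6.34 to 7.2 on exposed and 4.47 to 4.83 on control arrays. Of 16 p53 targets 8 rose and 3 fell, and 9 and 3 when adjusted over the list alone, with ZMAT3 at 1.31 ± 0.19, GADD45A at 1.20 ± 0.13 and CDKN1A at 1.15 ± 0.09 (adjusted p = 0.00382, adjusted p = 0.0659 with an estimated correlation). In the list of NRF2 targets and metallothioneins 9 of 18 rose and 1 fell, and 11 and 2 when adjusted over the list alone (adjusted p = 0.00241, adjusted p = 0.0889 with an estimated correlation). NQO1 rose by 1.63 ± 0.19 and HMOX1 by 1.34 ± 0.13, and the metallothionein gene MT3 fell by 0.97 ± 0.15.

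Of 11 antigen presentation genes 8 rose, and 9 when adjusted over the list alone, with the class II genes SLA-DRA at 0.63 ± 0.13, SLA-DQA1 at 0.62 ± 0.14 and SLA-DQB1 at 0.59 ± 0.14 (adjusted p = 0.00435, adjusted p = 0.325 with an estimated correlation); at 168, 336 and 514 h 7, 1 and 0 rose. Of 18 complement genes 9 rose, and 13 rose and 2 fell when adjusted over the list alone, with C3 at 1.94 ± 0.28 and C4A at 1.03 ± 0.19 (adjusted p = 0.00379, adjusted p = 0.325 with an estimated correlation). At 168 h 13 rose and at 336 h 3, while at 514 h 0 rose and 2 fell (medians 1.202, 0.402 and -0.094). Of 19 interferon-stimulated genes 6 rose, and 9 when adjusted over the list alone (median 0.608, adjusted p = 0.00962, adjusted p = 0.517 with an estimated correlation). Of 18 heat shock genes 9 rose, as when adjusted over the list alone, with HSPA4 at 0.54 ± 0.09 (adjusted p = 0.0188, adjusted p = 0.374 with an estimated correlation). Of 14 immediate early genes 6 rose and 1 fell, as when adjusted over the list alone, with FOS at 1.71 ± 0.36 and ATF3 at 1.18 ± 0.22 (adjusted p = 0.0288, adjusted p = 0.443 with an estimated correlation), and at 514 h alone 0 passed (median 0.017). With the muscle score as a covariate the calls of the interferon and immediate early lists were lost, the latter also in 6 of 18 fits that left out 1 array. Of 13 differentiated keratinocyte genes 6 fell and 3 rose, and 7 and 3 when adjusted over the list alone (median -0.254, adjusted p = 0.000991, adjusted p = 0.325 with an estimated correlation). At 168 h 10 fell and 0 rose (median -1.191), at 336 h 2 fell and 1 rose (-0.17), and at 514 h 0 fell and 3 rose (0.366). KRT1 fell by 1.75 ± 0.15 (5 of 9 pairs) and KRT10 by 1.41 ± 0.15 (7 of 9 pairs), while IVL, the involucrin gene (0.93), KLK7, a desquamation protease gene (0.61), and SFN (0.33) rose; these 3 were chosen after their values were seen. Of 17 adipocyte genes 9 fell and 1 rose, and 12 and 1 when adjusted over the list alone (median -0.42, adjusted p = 0.000694, adjusted p = 0.225 with an estimated correlation). The lipase gene LIPE fell by 0.71 ± 0.15, RBP4 by 0.69 ± 0.18 and GPD1 by 1.12 ± 0.35, and the call of GPD1 was lost with the muscle score as a covariate and without control 168 h replicate 3 or control 514 h replicate 1.

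The other lists missed the threshold in camera at 168 to 514 h. With the mean of all probe sets of a gene camera called fibroblast genes, downwards, and activated keratinocyte and apoptosis genes, upwards (adjusted p = 0.0493, 0.0493 and 0.047). With the muscle score as a covariate it called fibroblast genes, downwards (adjusted p = 0.00472). In the main fit none of these lists was called at an estimated correlation. MGMT rose by 1.21 ± 0.11 and PCNA by 0.54 ± 0.08 in the DNA repair list (5 of 16 rose, as when adjusted over the list alone, adjusted p = 0.122). JCHAIN, the immunoglobulin joining chain gene, rose by 2.16 ± 0.47 in 9 of 9 pairs in the lymphocyte list (4 of 17, and 5 when adjusted over the list alone, adjusted p = 0.105). AREG rose by 1.40 ± 0.14 (activated keratinocyte, adjusted p = 0.104), CASP1 by 0.81 ± 0.23 (apoptosis, adjusted p = 0.0696), NFIL3 by 0.97 ± 0.16 with CRY2 at -0.66 ± 0.10 (circadian, adjusted p = 0.164), and DST fell by 0.72 ± 0.09 (basal keratinocyte, median 0.0361, mean -0.0546, adjusted p = 0.449). Fibroblast genes had a median of -0.124 and a mean of 0.00628 (5 rose and 8 fell of 22, as when adjusted over the list alone, adjusted p = 0.0891). DPT, the dermatopontin gene, fell by 1.09 ± 0.13 and THBS1 rose by 1.23 ± 0.20. In the smooth muscle list RGS5 rose by 0.57 ± 0.15 and MCAM by 0.55 ± 0.12, with DES at -1.28 ± 0.39 (median 0.221, adjusted p = 0.164), and the call of DES was lost with the muscle score as a covariate, with sham arrays as the control group and without control 168 h replicate 3. HIF1A rose by 0.47 ± 0.10 in the endothelial list (adjusted p = 0.564), and VEGFA fell by 0.60 ± 0.09 while another of its probe sets was called higher. CIDEA fell by 0.57 ± 0.15 (hair follicle and sebaceous gland, adjusted p = 0.0818) and FABP5 rose by 0.51 ± 0.06 (epidermal lipid, adjusted p = 0.657). Melanocyte markers had a median of 0.00847, a mean of -0.0221 and an adjusted p of 0.564. The red blood cell list had 4 measured genes, too few for the test, and its gene HBB fell by 0.41 ± 0.12 at 24 to 72 h and by 0.45 ± 0.12 at 168 to 514 h.

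At 168 h ARG1 rose by 6.28 ± 0.74 and CXCL8 by 6.12 ± 0.70, and KRT1 fell by 5.23 ± 0.27 and KRT2 fell by 4.66 ± 0.61 (n = 3 pairs). At 336 h CXCL8 rose by 4.27 ± 0.70 and MMP1 by 3.90 ± 0.57, both of which missed the threshold when fitted on the 6 arrays alone, and KRT2 fell by 2.79 ± 0.61 and QPCT fell by 2.37 ± 0.24. KRT1 differed by -0.14 ± 0.27 at 336 h and 0.13 ± 0.27 at 514 h (adjusted p = 0.909 and 0.851). On the exposed arrays of these times it lay at 13.84 to 14.3, close to the highest values of the arrays (14.359 to 14.537), so a difference at the top of the scale cannot be excluded. On the control arrays of 168 h KRT1 lay at 14.1 to 14.24, so its fall at that time may be larger than given. On the exposed arrays of 168 h KRT1 ranged from 7.97 to 10.22. At 514 h S100A9 rose by 3.69 ± 0.69 and ARG1 by 3.51 ± 0.74, a call lost without exposed replicate 2 and when fitted on the 6 arrays alone, and SCARA5 and MYOC fell by 2.06 ± 0.30 and 1.85 ± 0.38. Without 1 array the count at 336 h was 450 (exposed 1), 432 (exposed 2), 490 (control 2) or 575 (control 3), and at 514 h 638 (exposed 1), 591 (control 1) or 394 (exposed 2).

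**Figure D3:**
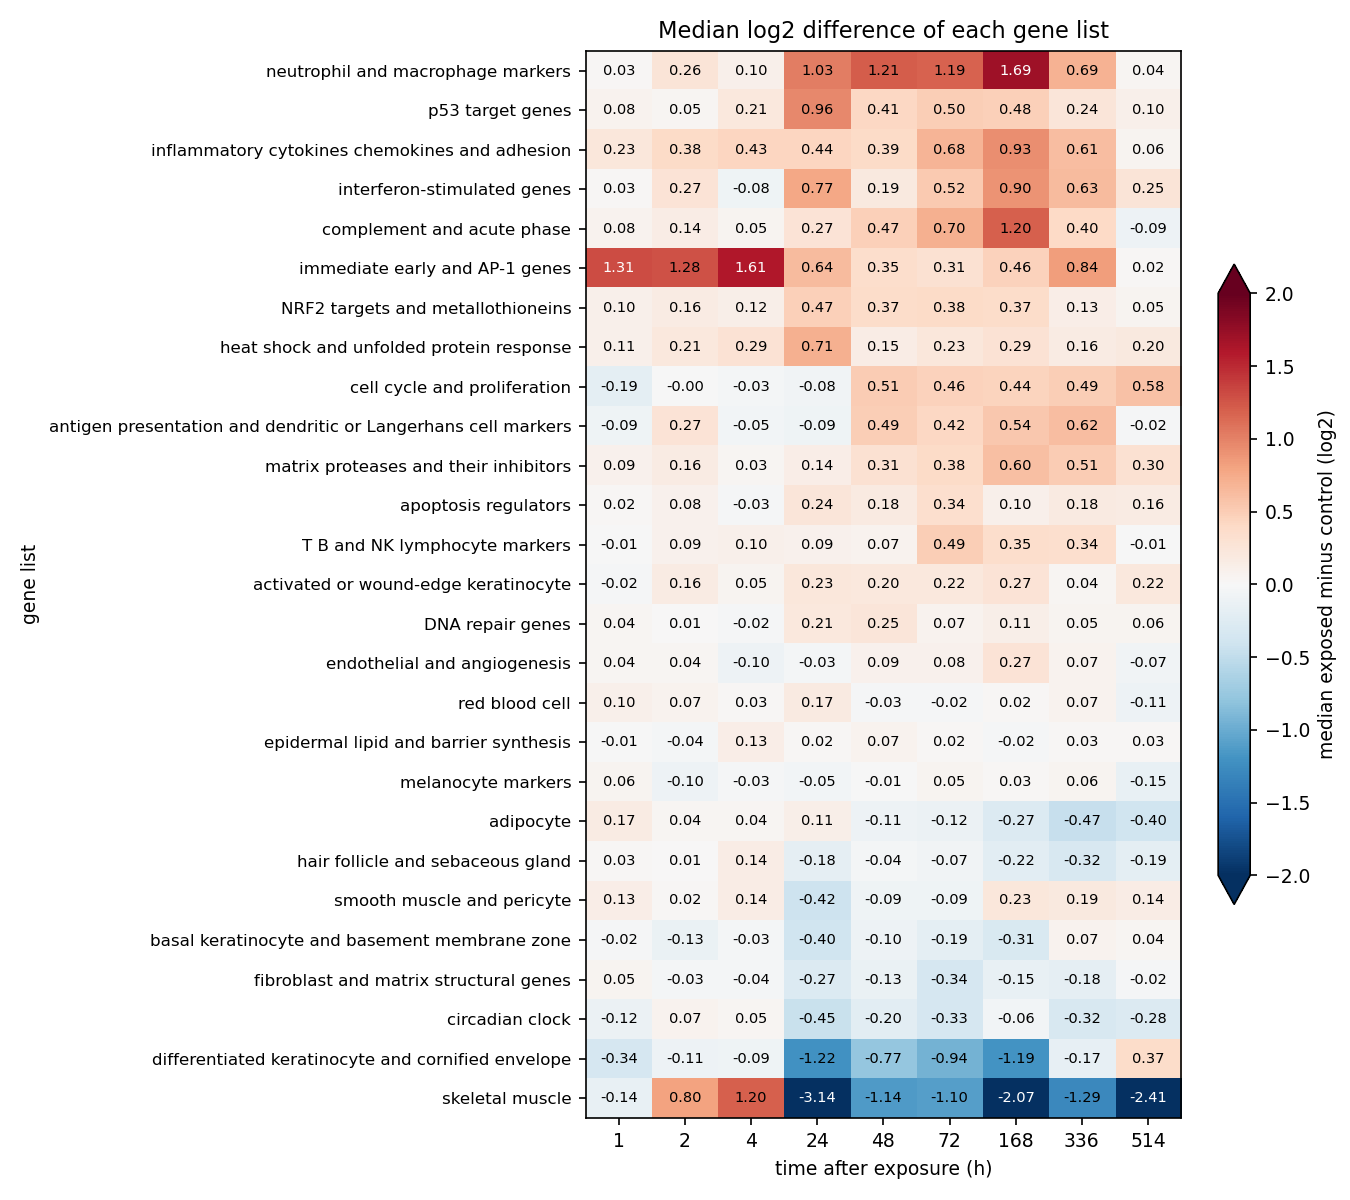
Median exposed minus control difference (log2, colour and number) of the measured genes of each of the 27 gene lists at each time after exposure (h). Immediate early genes have medians of 1.31, 1.28 and 1.61 at 1, 2 and 4 h, and differentiated keratinocyte genes -1.22 at 24 h and -1.19 at 168 h.

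The test of the difference between windows asked which responses came or went with time. From 1 to 4 h to 24 to 72 h, ARG1 gained 5.29 ± 0.60 (adjusted p = 4.41e-08), PPBP 4.72 ± 0.41, CXCL8 4.35 ± 0.57, TNC 3.22 ± 0.33 and CYP2C91 2.96 ± 0.26 on the log2 scale. CALML5, KRT2, SULT1E1, SERPINB7 and STMN2 had the largest losses, from -2.77 ± 0.26 to -2.29 ± 0.38. In all 3969 probe sets differed, 2427 upwards and 1542 downwards. From 24 to 72 h to 168 to 514 h, LOC396867 gained 2.49 ± 0.27, SERPINB7 2.03 ± 0.29, LGALS4, a galectin gene, 1.84 ± 0.37 and CALML5 1.77 ± 0.26, while PPBP (-3.33 ± 0.41), PTX3 (-2.16 ± 0.29), AMELX (-1.92 ± 0.26), MEDAG (-1.66 ± 0.22) and STC1 (-1.64 ± 0.34) decreased. Here 2028 probe sets differed, and 3082 with the replicate number as a block. A test of any difference among the 9 times called 4496, and there the times also differ in processing period.

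Calls overlapped between windows, which share no arrays. Of the 496 probe sets higher at 1 to 4 h, 283 were also higher at 24 to 72 h, where 90.5 would be shared if the calls were independent, and of the 819 lower ones 533 were shared (138 if independent). Of the 4378 higher at 24 to 72 h, 1904 were higher at 168 to 514 h (527 if independent), and of the 4054 lower ones 1522 were shared (401 if independent). The Pearson correlation of the log2 differences over probe sets, which are not independent replicates, was 0.346 between 1 to 4 h and 24 to 72 h, 0.74 between 24 to 72 h and 168 to 514 h, and 0.135 between 1 to 4 h and 168 to 514 h.

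The comparison with sham animals, over all 9 times, measured what differed between sites without exposure. HOXA9, a homeobox gene of positional identity, was lower in sham than in control sites by -1.74 ± 0.16 (n = 9 and 27 arrays, adjusted p = 2.09e-09). Its values were 7.19 to 8.66 in sham, 8.68 to 10.33 in control and 6.26 to 9.35 in exposed arrays. The 4 other probe sets called were also lower. They were NME6 (-0.27 ± 0.05), SPATA4 (-0.20 ± 0.04) and 2 without a gene symbol (-0.71 ± 0.11 and -1.61 ± 0.28). These last 2 were also lower in exposed sites, by -0.647 and -1.481 at 24 to 72 h (adjusted p = 0.000225 and 0.000743) and by -0.577 and -1.559 at 168 to 514 h (adjusted p = 0.00166 and 0.000812), while at 1 to 4 h they missed the threshold (-0.407 and -0.623, adjusted p = 0.0782 and 0.409). The calls of NME6 and SPATA4 were lost when limma was fitted on sham and control arrays alone. That fit left 1 call, so at least 1 of the 2 probe sets without a gene symbol lost its call too. Of 23999 probe sets 2168 had an unadjusted p below 0.05. The count was 3 without the sham array of 1 h, 72 h or 168 h and 2 without that of 4 h or 48 h.

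In camera 3 lists were higher and 7 lower in sham than in control sites; with an estimated correlation 0 were called (1 at an unadjusted p below 0.05), and fry called 0 (4 at an unadjusted p below 0.05). In each of these lists 0 genes passed in limma over all probe sets. Skeletal muscle genes had a median of -1.81 (20 of 22 lower when adjusted over the list alone, 20 at an unadjusted p below 0.05, adjusted p = 1.43e-12, adjusted p = 0.427 with an estimated correlation). The muscle score was 11.6, 8.71 and 7.25 in the 3 sham arrays of each window, from the first to the last. Interferon-stimulated genes had a median of -0.268 (4 of 19 at an unadjusted p below 0.05, adjusted p = 0.000586, adjusted p = 0.475 with an estimated correlation). Fibroblast genes had a median of 0.134 (7 of 22, adjusted p = 2.12e-06) and differentiated keratinocyte genes of 0.178 (4 of 13, adjusted p = 0.000586). The medians of the inflammatory (6 of 33), neutrophil and macrophage (2 of 22), lymphocyte (1 of 17), antigen presentation (4 of 11) and complement lists (2 of 18) were -0.0638, -0.101, -0.0872, -0.123 and -0.109, and that of the heat shock list (3 of 18) 0.0697, with an adjusted p of 0.00413 to 0.0224. For all of these lists adjusted p = 0.427 with an estimated correlation. Adjusted over the list alone, 1 fibroblast, 2 differentiated keratinocyte and 1 heat shock gene were higher and 1 complement gene was lower. Of 36 fits that left out 1 array the call was lost in 8 for antigen presentation, 5 for heat shock, 4 for complement, 2 for inflammatory and 1 for neutrophil and macrophage genes. The 16 other lists had an adjusted p of 0.0676 to 0.989.

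**Figure D4:**
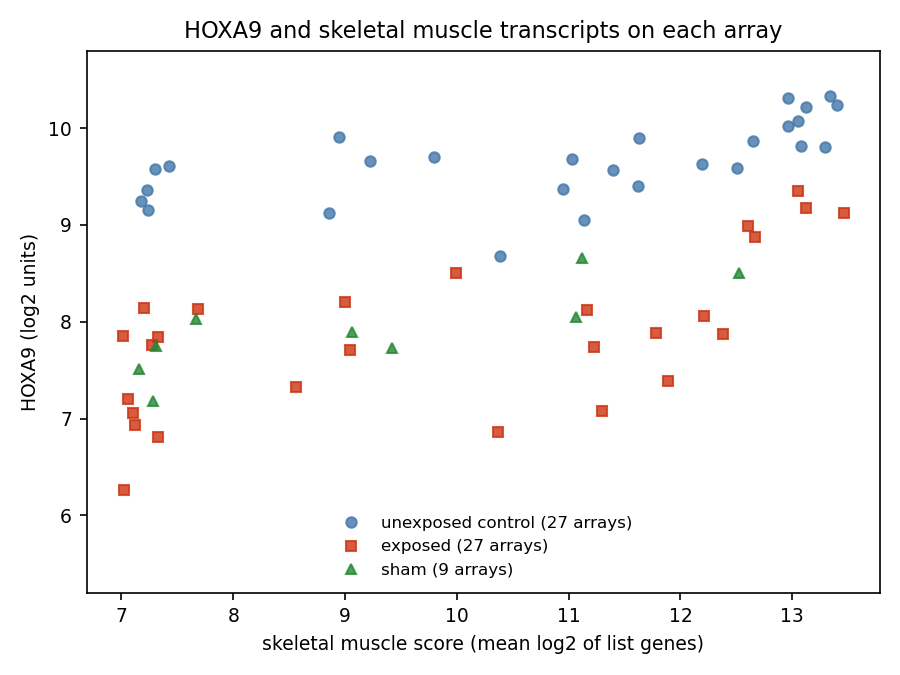
HOXA9 (log2 units) against the skeletal muscle score (mean log2 value of the muscle list genes) on each of the 27 control, 27 exposed and 9 sham arrays. Control arrays lie at 8.68 to 10.33 for HOXA9 and sham arrays at 7.19 to 8.66, at muscle scores of 7.176 to 13.4 and 7.155 to 12.52.

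The size of the change was also compared with the length of the gene in the assembly, which is not the length of its transcript. Over 6694 genes with a length, Spearman's rho between the log2 difference at 1 to 4 h and gene length was -0.378, a correlation across genes, which are not independent replicates. At single times it was -0.203 at 1 h, -0.379 at 2 h and -0.332 at 4 h. At later times it was -0.168 at 24 h, -0.21 at 48 h and -0.0991 at 72 h (-0.175 at 24 to 72 h), and -0.0343, -0.0989 and 0.000142 at 168, 336 and 514 h (-0.0523 at 168 to 514 h). For sham against control sites it was 0.055. Genes called higher at 1 to 4 h had a median length of 6115 bp and genes called lower of 93228 bp, against 21561.5 bp for all genes. With the genes in 5 groups of equal size by length, 4 of the longest group were called higher and 118 lower, and 103 and 7 of the shortest.

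**Figure D5:**
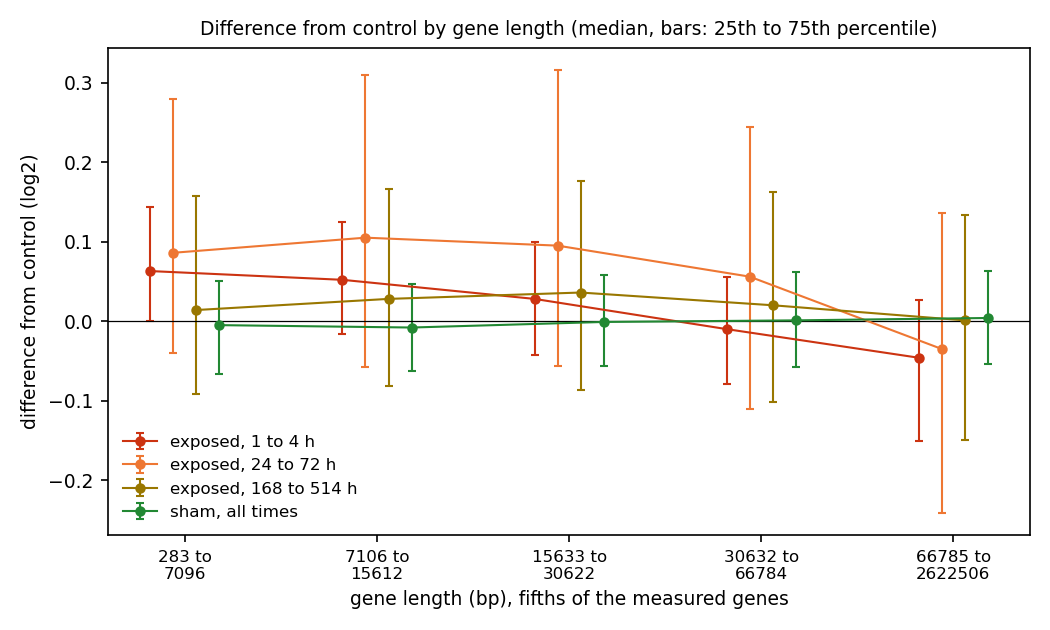
Median difference from control (log2) of the genes in each of 5 groups of gene length (bp), with bars from the 25th to the 75th percentile, for the 3 windows of exposure and for sham sites. At 1 to 4 h the median goes from 0.063 in the shortest group to -0.046 in the longest, and in sham sites from -0.005 to 0.004.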

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

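In this part the tests of exposure as the cause of the HOXA9 and muscle differences and of the position of the sites were chosen only after the result was seen, as were the muscle score as a covariate and the count of lists over exchanges within pairs. The responses that differed between times by the test of the difference itself were the 3969 probe sets between 1 to 4 h and 24 to 72 h, the 2028 between 24 to 72 h and 168 to 514 h, and the 4496 among the 9 times. Among named genes the first of these differences was 5.29 for ARG1, 4.72 for PPBP, 4.35 for CXCL8, 3.22 for TNC and 2.96 for CYP2C91. It was -2.77 for CALML5, -2.75 for KRT2, -2.73 for SULT1E1, -2.72 for SERPINB7 and -2.29 for STMN2. The second difference was 2.49 for LOC396867, 2.03 for SERPINB7, 1.84 for LGALS4, 1.77 for CALML5 and 1.75 for ADAMDEC1, whose call was lost with the RNA extraction batch as a covariate and in 9 of 36 fits that left out 1 array. It was -3.33 for PPBP, -2.16 for PTX3, -1.92 for AMELX, -1.66 for MEDAG and -1.64 for STC1.

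The same arrays were also split in other ways, to see what an arbitrary division of the samples gives. For the windows chance can be excluded: the real split gave 1315, 8432 and 5262 probe sets, the highest of the other 99 splits 56, 5687 and 1608, and each real count was reached by 1 of 100. For the differences between windows the real counts were again reached by 1 of 100 (3969 against 594 and 2028 against 578). Those exchanges put arrays of different times into the same group. Differences between times then add to the spread within groups and lower the other counts, so this test does not exclude chance. For any difference among times the real count was also reached by 1 of 100 (4496 against 1), but those exchanges crossed the processing periods. Differences between periods and times then add to the spread within groups and lower the other counts, so this test does not exclude chance. Where exposed and control arrays were exchanged within pairs of the same number, the highest counts of the windows were 222, 7816 and 1429.

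For the single times the 10 splits of 6 arrays cannot give a share below 0.1, so chance cannot be excluded; the real count was reached by 1 of 10, and by 2 of 10 at 2 h. The real counts and the highest others were 288 and 159 at 1 h, 348 and 204 at 4 h, 6507 and 356 at 24 h, 2387 and 877 at 48 h, 2317 and 69 at 72 h, 4304 and 17 at 168 h, 970 and 107 at 336 h and 1398 and 3 at 514 h. At 2 h the real split gave 94 and another 451, which points to a structure of the samples. That split set exposed 1, exposed 2 and control 2 against the rest, so it kept the pairs numbered 2 and 3 together; with the number as a block the count at 2 h was 149. Among the 4 splits of each time that part all 3 pairs, as the real one does, the real one was highest at all 9 times, and the others, which exchange exposed and control in 1 pair, gave at most 417.

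For sham against control chance cannot be excluded, with 13 of 100 splits giving as many as 5 probe sets and the highest 529, which points to a structure of the samples. The number of lists called was 6 at 1 to 4 h, where 41 of 100 splits gave as many (highest 12), and 13 at 24 to 72 h, where 5 of 100 did (highest 15), so chance cannot be excluded for either count. At 168 to 514 h 2 of 100 splits, the real one included, gave as many as 14 lists (highest other 14), a share below 0.05. That share is not corrected for the other list counts tested, so it argues against chance without excluding it. For sham chance cannot be excluded (10 lists, 5 of 100, highest 11). Where exposed and control arrays were exchanged within pairs of the same number, 33, 6 and 3 of 100 gave as many lists in the 3 windows, with 14, 13 and 15 the highest others.

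HOXA9 was lower in exposed and in sham sites than in unexposed control sites, and a biologist would want to know what marks the control sites. Exposure as the whole cause is argued against by the sham sites, which were not exposed and lay at -1.741 ± 0.155 from the control sites; exposed and sham sites differed by 0.105, -0.51 and 0.224 in the 3 windows (adjusted p = 0.923, 0.156 and 0.647). Muscle content is argued against too, since the difference of sham from control stayed at -1.563 with the muscle score as a covariate. A position of the control sites apart from the others on the abdomen is a candidate explanation that stays open, since the labels give no site positions. In sham against control 0 of the 5 other measured HOX genes passed in limma when adjusted over those genes alone (1 at an unadjusted p below 0.05). In exposed sites all 5 were lower at 24 to 72 h (HOXA3 -0.715, HOXB7 -0.309, HOXD10 -0.371, HOXD12 -0.994, HOXD8 -0.42) and at 168 to 514 h (-0.36, -0.408, -0.179, -0.777 and -0.492), and at 1 to 4 h only HOXD12 was (-0.425). MEIS1 was lower in all 3 windows (-0.359, -0.712 and -0.812), with 0.102 in sham sites (adjusted p = 0.783). HOXA9 is not alone in part of its pattern. The 2 probe sets without a gene symbol were lower in sham sites (-1.611 and -0.709), at 24 to 72 h (-1.481 and -0.647) and at 168 to 514 h (-1.559 and -0.577). At 1 to 4 h, where HOXA9 was called, they missed the threshold in limma (-0.623 and -0.407, adjusted p = 0.409 and 0.0782). At least 1 of them also lost its sham call when sham and control arrays were fitted alone. A record of the positions may settle it.

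Transcripts of skeletal muscle differed widely between arrays of the same group. Muscle tissue in some biopsies is a candidate explanation: the measured muscle genes moved together over the 27 control arrays, with a median pairwise Pearson r of 0.948, and the abundant genes CKM and MYL1 ranged from 8.18 to 14.06 and from 6.06 to 14.15 on those arrays. Exposure as the whole cause is argued against by the range of the muscle score over control arrays alone, 6.22 on the log2 scale. A difference in muscle between exposed and control sites is left open by the exact permutation within times (p = 0.0107 at 24 to 72 h, adjusted p = 0.128), and depth of the biopsies, which the labels do not give, would test it.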

How the results depend on the processing

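The covariate for the muscle score and the use of sham arrays as the control group were chosen after seeing the data; all others were chosen before the data were examined. Quantile normalization applied again, median centring, the intensity trend and the in vitro transcription batch left every count of probe sets within 1.5 times its value. Of these 4 only quantile normalization was also run for the lists, where it called 4, 13, 14 and 10. The largest median difference over all probe sets in these scalings was 0.03, at 1 h with median centring; there the share of higher probe sets went from 34.4% to 44.6%. Of 277 named gene results past the threshold, 237 stayed past it under every choice made in advance of test, scaling, batch, control and block, and 240 in every fit that left out 1 array. Stricter thresholds are not part of the 237. An adjusted p of 0.01 ended 39 of the 277 calls and a log2 change of at least 1 ended 98. The replicate block, run for 274 of them, lost 0, and it added the calls of NEB at 24 to 72 h (-2.416, adjusted p = 0.0336) and MITF at 168 to 514 h (-0.254, adjusted p = 0.00892). It gave 436 probe sets at 1 h, 149 at 2 h, 606 at 4 h, 1736 at 336 h, 2162 at 514 h and 3082 for the later difference between windows; the cause was not tested. Signal close to background limits what can be said of genes near the lowest values, about 4.05. Leaving out dim probe sets ended 0 of the 238 named calls that it kept, of 277. The calls that it removed were those of dim probe sets, so this setting does not test them. Differences of the brightest genes are limited by the top of the scale, at 14.54.

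Stricter thresholds lower counts by construction. At an adjusted p of 0.01 the counts were 113 at 1 h, 195 at 4 h, 1140 at 48 h, 1293 at 72 h, 2553 at 168 h, 444 at 336 h, 510 at 514 h, 625 at 1 to 4 h, 3360 at 168 to 514 h, 2338 and 870 for the differences between windows, 2 for sham and 2601 among the 9 times. With a log2 change of at least 1 they were 55, 50, 110, 1249, 370, 446, 916, 292 and 184 at the 9 times, 70, 520 and 344 in the windows, 388 and 140 for the differences and 2 for sham. Among the times, where the range of the 9 differences had to be at least 1, the count was 2280. Fitted on the arrays compared alone, with fewer arrays to estimate the spread, they were 1 at 1 h, 0 at 2 h (1180 at an unadjusted p below 0.05 in limma), 60 at 4 h, 924 at 48 h, 1168 at 72 h, 815 at 1 to 4 h and 1 for sham. For sham the count was 2 without dim probe sets, 3 with the RNA extraction batch and 2 with the muscle score. With control and sham merged it was 571 at 4 h, 3789 at 48 h and 1481 at 336 h. With sham arrays as the control group, 1 array at each time, it was 300 at 1 to 4 h (171 higher, 129 lower, against 496 and 819) and 2468 at 168 to 514 h. The cause of these last changes was not tested.

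Of the lists, camera with an estimated correlation called 3, 2, 1 and 0 in the 3 windows and for sham, and fry 20 at 24 to 72 h and 0 for sham (4 at an unadjusted p below 0.05). The replicate block, run for the 3 windows, called 7, 15 and 16, losing 0 and adding 1 (downwards), 2 and 2, and the block changed no other call of a named gene or list. For every called list the estimated correlation gave the highest adjusted p among its alternatives, except skeletal muscle at 168 to 514 h (0.717) and for sham (0.811), where the muscle score did by construction. Results that reversed were HOXA9 with sham arrays as the control group (0.105 at 1 to 4 h and 0.224 at 168 to 514 h), CKM (0.093) and TNNC1 (0.055) at 168 to 514 h and DES (0.014) at 24 to 72 h in the same setting, and HSPA8 at 1 to 4 h with the mean of all probe sets (-0.029); the cause was not tested. With the muscle score the skeletal muscle list for sham had a median of 0.039, by construction, since the score is the mean of those genes. The muscle score ended 19 of 277 named calls, 4 of them of genes that are part of it, and sham arrays as the control group 52 of 219. With the muscle score the 5 sham calls went to 2.

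Leaving out each array in turn gave counts of 85 to 461 at 1 h (without control 1 and control 3), 47 to 114 at 2 h (control 1, exposed 3), 218 to 598 at 4 h (control 2, control 1), 1097 to 2610 at 48 h (control 2, control 1), 1081 to 2650 at 72 h (exposed 3, exposed 2), 432 to 1201 at 336 h (exposed 2, exposed 3), 394 to 1402 at 514 h (exposed 2, exposed 3) and 2 to 7 for sham. The number of lists called for sham was 5 to 13, with 5 without the sham array of 72 h. All other counts stayed within 1.5 times their value.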

Other observations

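In this part the genes, and the tests with actin and EF1A, were chosen after the values were seen. Some genes were called in opposite directions in successive windows, though such calls were fewer than independent calls would give. Between 1 to 4 h and 24 to 72 h there were 60 such probe sets, against 233 if independent. Between 24 to 72 h and 168 to 514 h there were 97, against 921. Of 19 genes with opposite calls between 1 to 4 h and 24 to 72 h, 13 were lower first. The Notch target gene HES1 went from 0.34 ± 0.09 to -0.80 ± 0.09, the homeobox gene DLX5 from 0.54 ± 0.16 to -0.57 ± 0.16 and CITED2 from 0.56 ± 0.08 to -0.22 ± 0.08. The chromatin remodelling gene SMARCA4 went from -0.34 ± 0.07 to 0.42 ± 0.07, SOCS6 from -0.32 ± 0.09 to 0.40 ± 0.09, the stem cell factor gene KITLG from -0.27 ± 0.07 to 0.20 ± 0.07 and CHEK2, a DNA damage checkpoint kinase gene, from -0.21 ± 0.06 to 0.24 ± 0.06.

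Between 24 to 72 h and 168 to 514 h there were 33 genes with opposite calls, of which 23 were lower first. KLK7 went from -0.88 ± 0.17 to 0.61 ± 0.17, CRABP2, which binds retinoic acid, from -0.55 ± 0.20 to 0.65 ± 0.20, SFN from -0.38 ± 0.13 to 0.33 ± 0.13, the thrombospondin gene THBS2 from -0.58 ± 0.12 to 0.38 ± 0.12, the integrin gene ITGA8 from -0.46 ± 0.11 to 0.53 ± 0.11 and TGFB3 from -0.29 ± 0.08 to 0.29 ± 0.08. The receptor gene BMPR1B went from -0.65 ± 0.11 to 0.44 ± 0.11 and was also lower at 1 to 4 h (-0.51 ± 0.11). MEDAG went from 1.13 ± 0.16 to -0.53 ± 0.16 and the procollagen enhancer gene PCOLCE2 from 0.34 ± 0.09 to -0.88 ± 0.09.

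Longer genes tended to be lower in exposed sites at 1 to 4 h, with a Spearman rho of -0.378 across genes, and at 24 h and 48 h as well (-0.168 and -0.21). The brightness of the probe sets with the short induced genes is argued against, since rho was -0.343 given mean log2 and without the genes called higher. Degraded RNA stays open. Gene length here reaches 2622506 bp and is not transcript length, so rho does not test degradation of the mature RNA directly. With the GAPDH 3 prime minus 5 prime difference as a covariate rho was -0.375, but that difference followed the muscle score (r = -0.82), so it does not test degradation. With those of actin and EF1A rho was -0.376 and -0.373, and 1 bright transcript each does not show how well the RNAs of long genes were kept. For exposure, over 100 exchanges of exposed and control within same-numbered pairs 3 gave a rho as far from 0, the real one included, with 0.389 the highest other in size. A block of transcription by DNA adducts, in proportion to the length of the gene, is a candidate explanation that stays open beside degradation; it was found on the same data, and nascent RNA or intron signal over long genes would test it.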
